A study of Rattus norvegicus with 2 samples.

How the data were processed

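Total RNA from cultured rat neural precursor cells was hybridised to 2 two-colour Agilent rat expression arrays, both on 1 slide and read in 1 scan. Per the labels, the red channel (Cy5) of the withdrawal array held RNA from cells carrying the empty vector without bFGF. The red channel of the other array held RNA from cells carrying rat Bcl-2 with bFGF, and the green channel (Cy3) of both arrays held RNA from cells carrying the empty vector with bFGF. Each comparison has 1 array and no dye swap.

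The deposited scanner files give, per the file headers, spot and local background intensity as the median over pixels, not normalized, for each channel. They were made with Feature Extraction 11.5.1.1 and protocol GE2_1105_Oct12 on a G2505C scanner with array design 028282 and build rn4, while the submitters' processing notes name Feature Extraction 8.5.1.1. The same files hold the deposited log10 ratio of red over green with its error, and a deposited p-value of that log ratio from the spot noise model, which covers no difference between samples. Other deposited columns are flags of 0 or 1 for outlier, saturated and well above background, per the file headers.

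The authors' deposited value table holds a linear ratio in 2 columns of 29782 probes, with medians 0.932 and 0.944. Its scale, centring and direction are not stated in the sources used here. They were found by setting each column against the processed scanner signals over 28395 probes printed once. Within 0.05 on the log2 scale and after a constant, the first column equalled red over green of the withdrawal array for 100% of probes. The second column equalled the ratio of its own array for 7.06% of probes and the product of the ratios of both arrays for 100%. As an alternative, the first column was used for the withdrawal array and the quotient of the columns for the other array.

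Median signals were used because the files hold no mean signals, which the plan had assumed. Signals were background-corrected by normexp with an offset of 50 and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Gene lists and counts were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Of 44254 spots, 42877 carried 30367 probes for genes and 1377 were controls. Outlier spots (534 on the withdrawal array and 576 on the other) were left out, and 0 spots were saturated. Spots of a probe were averaged, and a probe was kept if well above background in at least 1 channel, which left 20328 and 19026 probes.

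The files give no gene symbols. Accessions without version were matched to a RefSeq gene table of assembly GRCr8, used for names alone, and 60.4% of the probes were named. The value of a gene is the median over its kept probes, which gave 10852 genes on the withdrawal array and 10241 on the other. Of these, 1863 and 1738 genes had 2 or more kept probes, and the kept probes of 534 and 538 of them disagreed in sign. The other genes rest on 1 probe and have no such check. Where a gene was well above background in 1 channel alone, the fold is given as "at least". It sets the bright channel against the higher of the dim signal and the lowest signal well above background, after loess and Aquantile scaling, and is open to dye bias.

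With 1 array per comparison there is no test and no p across genes. A gene was counted, and is called at least 2-fold, if its absolute log2 ratio was at least 1 and all its kept probes had the same sign. For 3 counted genes on the withdrawal array and 4 on the other, dim in 1 channel, the "at least" fold was under 2. Each of 24 gene lists is described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on intensity. A list stands apart under percentile 2.5 or over 97.5, and about 1.2 of 24 lists of independently drawn genes would do so by chance. Genes of a list may vary together and some lists share members, so that number may be too low. The number of lists standing apart is therefore a description and not a test. The lists cover neuronal structure and synapse, neurogenic transcription factors, GABAergic and glutamatergic neuron markers, neural stem and progenitor cells and the cell cycle. Signalling lists are FGF and ERK response, BMP and TGF-beta, Notch, Wnt, BCL-2 family and apoptosis and p53 targets. Metabolic and stress lists are unfolded protein and integrated stress response, cholesterol synthesis, antioxidant and metallothionein, glycolysis and hypoxia response, and interferon response. Marker lists of other cell types are astrocyte, oligodendrocyte lineage, microglia and blood, endothelium and pericyte, fibroblast and meninges, and choroid plexus and ependyma. Ribosomal proteins serve as a reference list.

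Named genes were taken by a rule: Bcl2, then the 10 highest and 10 lowest genes at least 2-fold in both the loess ratio and the Feature Extraction ratio, leaving out names that are only identifiers. To these were added up to 4 members with the largest absolute ratio of each list that stood apart, and Tubb3, Dcx, Map2, Nes, Sox2, Mki67, Gfap, Bmp4 and Ccnd1. For genes at least 2-fold on both arrays, the 5 highest and 5 lowest by the smaller absolute ratio were taken. Groups, lists, the rule and the alternatives were fixed before the data were examined, except where the text says otherwise. The alternatives were other background corrections, median centring, the Feature Extraction ratio, the value table, other filters on dim probes, the brightest probe, leaving out saturated spots, a 1.5-fold limit, a Feature Extraction p under 0.01, list means, and red channels set against each other.

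The steps were tested on simulated data. Of 100 spots changed by 1.5 on the log2 scale, 100% were recovered at the 2-fold limit on each array, and 0% of 16327 and 15996 unchanged spots were called. All these spots were bright in green, with simulated noise of SD 0.1 and no gene-specific dye bias. Dim spots and spots measured in 1 channel alone were therefore not tested. Of 100 random lists of 20 genes on the withdrawal array, 8% stood apart unchanged and 98% did so after a shift of 0.3. Of 100 lists of 10 genes, 74% did so after that shift, so a list with few measured members can be missed. The number of arrays limits the precision. Probes printed 10 times and well above background had a median SD between spots of 0.037 on each array, which measures spot noise within an array and not the spread between cultures.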

Results

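Cortical neural precursor cells from rat embryos at day 14 were grown with 10 ng/mL bFGF, a growth factor that keeps such cells dividing. They were transfected with 4 µg of a plasmid carrying a fluorescent reporter alone (the vector) or together with rat Bcl-2, an inhibitor of mitochondrial apoptosis. Cells then either stayed with bFGF or were moved to another medium without it for 2 days. The withdrawal array set vector without bFGF (red) against vector with bFGF (green), which asks what differentiation changes. The other array is labelled as Bcl-2 with bFGF (red) against vector with bFGF (green), which asks what Bcl-2 changes in dividing cells. Median net signals were 189 in green and 284.5 in red on the withdrawal array, with 66.3% and 72.0% of spots well above background. On the array labelled Bcl-2 they were 201 and 266, with 66.6% and 66.1%. There are no replicates, so no difference below has a replicate check, and each value describes these 2 arrays.

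The direction of the ratios is not settled. Arrays of the same dye orientation against 1 control RNA should correlate above 0 where the treatments change nothing, while opposite effects of the treatments could turn the sign. The log2 ratios of the arrays correlated at r = -0.67 over all gene spots, and at -0.12 with the Feature Extraction ratio. Values below are red over green as labelled. With the sign turned, higher becomes lower for every gene and list of that array: the 263 genes higher and 51 lower on the withdrawal array would be 51 higher and 263 lower, and the 57 higher and 205 lower on the array labelled Bcl-2 would be 205 higher and 57 lower.

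On the withdrawal array, genes of cholesterol synthesis were lower in the channel labelled without bFGF, and astrocyte genes, metallothioneins and p53 targets were higher. The 22 measured cholesterol synthesis genes all lay below 0, with a median log2 ratio of -1.13, and 15 were at least 2-fold lower. The astrocyte list had a median of 0.88, and 6 of its 13 measured members were at least 2-fold higher, led by Apoe, a lipid carrier, at 3.54 and Aldh1l1, a folate enzyme, at 2.61. Of 10852 genes, 263 were at least 2-fold higher and 51 at least 2-fold lower. The Feature Extraction ratio gave 887 and 237, and normexp with an offset of 10 gave 445 and 91.

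The Bcl2 probe had a log2 ratio of 0.39 on the withdrawal array. The highest genes were Apoe, the actin-binding gene Tagln at 3.23, the metallothioneins Mt1 at 2.73 and Mt2A at 2.47, and Ndrg2 at 2.71. They also included Aldh1l1, the NADPH oxidase subunit gene Cyba at 2.49, the cilium gene Pierce1 at 2.47 and the DNA repair gene Mgmt at 2.38. Mrgprf, not well above background in green, was at least 5.49-fold higher in red on this array and at least 4.03-fold higher in red on the other. The lowest genes were Cd93 at -1.92, Acss2, which makes acetyl-CoA from acetate, at -1.92, and the desaturase gene Scd at -1.55. The sterol pathway genes Idi1 at -1.66, Mvd at -1.62, Hsd17b7 at -1.55 and Acat2 at -1.55 were also among them, with Slc35d3 at -1.64, Zcchc12 at -1.51 and Ankrd37 at -1.48.

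**Figure D1:**
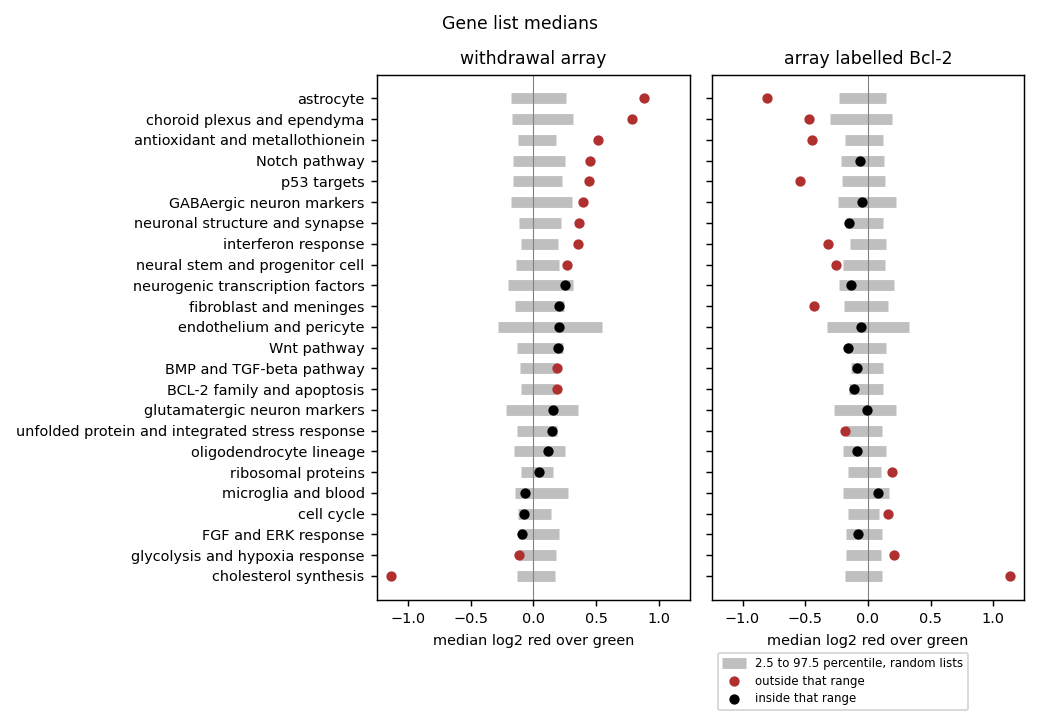
Median log2 ratio of red over green of each of 24 gene lists on the withdrawal array (left) and the array labelled Bcl-2 (right); grey bars span the range of random lists matched on intensity inside which a list does not stand apart, and red points lie outside it. Cholesterol synthesis lies at -1.13 on the left and 1.13 on the right, and astrocyte at 0.88 and -0.80.

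In all, 13 of the 24 lists stood apart on the withdrawal array, 11 higher and 2 lower. Cholesterol synthesis had percentile 0 and the astrocyte list percentile 100. The antioxidant and metallothionein list had a median of 0.51 (percentile 100), with 5 of 22 measured members at least 2-fold higher, among them the quinone reductase gene Nqo1 at 1.91 and Gsta1 at 1.19. The p53 targets had a median of 0.44 (percentile 99.96), and 3 of 15 were at least 2-fold higher: Tp53inp1 at 1.65, Ccng1 at 1.63 and the pro-apoptotic gene Bbc3 at 1.62. The interferon response list had a median of 0.35 (percentile 100), with Ifi27 at 1.27 and Gbp2 at 1.14 at least 2-fold higher among 20 measured. The choroid plexus and ependyma list had a median of 0.78 (percentile 100), and 1 of 8 measured members was at least 2-fold higher, the cilium regulator Foxj1 at 1.95, with Enkur at 0.91 and Ttr at 0.90.

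The neuronal structure and synapse list had a median of 0.36 (percentile 99.92), with 14 of 19 measured members above 0 and 5 below. Ncam1 at 1.04 and the neuronal tubulin gene Tubb3 at 1.03 were at least 2-fold higher, while Dcx was at 0.60 and Map2 at 0.42. The GABAergic list had a median of 0.40 (percentile 99.28), with 7 of 8 measured members above 0. The 1 below was Gad1 at -0.17, named here outside the rule. Dlx5, the 1 member counted as 2-fold, was at least 3.95-fold higher, not being well above background in green. Lhx6, also named outside the rule, was not well above background in green either, and Npy was at 0.78. Notch pathway genes had a median of 0.45 (percentile 99.96) with 0 of 14 at least 2-fold; Notch2 was at 0.84 and Hes5 at 0.61. The neural stem and progenitor list had a median of 0.27 (percentile 99.52), with the radial glia gene Fabp7 at 1.26 the 1 member at least 2-fold higher among 17, while Nes was at 0.18 and Sox2 at -0.12. Median centring without loess placed the neuronal list inside the random range, and so did the Feature Extraction ratio and the value table for the GABAergic list, at 0.33 and 0.29.

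The Feature Extraction ratio moved the fold of 12 of 68 measured named genes on the withdrawal array by over 1.5 times, all further from 0. Past the 2-fold limit by that ratio were Dcx at 1.38, Notch2 at 1.49, Npy at 1.27, Enkur at 1.65, Ttr at 1.28 and Bmp4 at 2.28. Pierce1 was at 3.12, Slc35d3 at -2.26, Ankrd37 at -2.43 and Gsta1 at 1.89.

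The BMP and TGF-beta list stood apart narrowly, at 0.19 (percentile 97.69), with Id4 at 1.27. The BCL-2 family and apoptosis list was at 0.19 (percentile 97.95), and glycolysis and hypoxia response at -0.12 (percentile 2.31), with Ankrd37 lower and Ddit4 at 1.44. Each of these 3 lay inside the random range under at least 4 alternatives. The cell cycle list did not stand apart, at -0.07 (percentile 12.34), with Mki67 at -0.00 and Ccnd1 at -0.93. Neither did FGF and ERK response at -0.09, neurogenic transcription factors at 0.25, glutamatergic neuron markers at 0.16, Wnt pathway at 0.20, unfolded protein and integrated stress response at 0.15 or ribosomal proteins at 0.05. Among markers of other cell types, oligodendrocyte lineage at 0.12, microglia and blood at -0.07, endothelium and pericyte at 0.20 and fibroblast and meninges at 0.21 did not stand apart. Some of these lists had few measured members, so a shift could be missed. They are endothelium and pericyte with 3 of 14 (random range -0.28 to 0.55), glutamatergic markers with 6 of 13 and neurogenic transcription factors with 8 of 22. Gfap was not well above background in either channel of either array. Bmp4 was kept on the withdrawal array alone, where it was at least 1.14-fold higher in red.

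On the array labelled Bcl-2, cholesterol synthesis genes were higher in red and astrocyte genes lower, the opposite of the withdrawal array. The Bcl2 probe, which should check the label, had a log2 ratio of -0.02. Whether that probe lies within the transfected sequence is not known here, so it checks little. The 22 cholesterol synthesis genes all lay above 0, with a median of 1.13 (-1.13 with the sign turned), and 14 were at least 2-fold higher, among them Lss at 1.43 and Idi1 at 1.38. The astrocyte list had a median of -0.80 (0.80 with the sign turned), and 4 of 13 members were at least 2-fold lower, including Apoe at -3.20, Aldh1l1 at -2.02 and the glutamine synthetase gene Glul at -1.13. Of 10241 genes, 57 were at least 2-fold higher and 205 at least 2-fold lower, so that 21.8% of counted genes were higher (78.2% with the sign turned); the Feature Extraction ratio gave 358 and 690, with 34.2% higher (65.8% with the sign turned).

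The highest genes included Cd93 at 2.00, Acss2 at 1.99, Slc35d3 at 1.72 and Mvd at 1.44. The others were measured in red alone: Mrgprf, Rab39a at least 3.51-fold, Mgat3 at least 3.24-fold, Milr1 at least 2.46-fold, Il22ra1 at least 2.18-fold and the olfactory receptor gene Or1e1 at least 1.93-fold higher. The lowest were Apoe, Tagln at -3.02, Cdh6 at -2.63, Mt2A at -2.55 and Cyba at -2.52. Cryab, a small heat shock protein gene, at -2.46, Pierce1 at -2.41, Mgmt at -2.39, the myosin light chain gene Myl9 at -2.38 and the collagen gene Col5a3 at -2.36 completed them.

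Of the 24 lists, 12 stood apart on this array, 4 higher and 8 lower. The p53 targets had a median of -0.54 (percentile 0), with Ccng1 at -1.49, Bbc3 at -1.31 and Tp53inp1 at -1.21 at least 2-fold lower. The fibroblast and meninges list was at -0.43 (percentile 0), and 5 of 12 members were at least 2-fold lower, with Acta2 at -1.93 and Col1a2 at -1.71. The antioxidant and metallothionein list was at -0.44, interferon response at -0.32, choroid plexus and ependyma at -0.47, neural stem and progenitor cells at -0.25 and unfolded protein and integrated stress response at -0.18. Higher lists were glycolysis and hypoxia response at 0.20, with Ankrd37 at 1.13 and the lactate dehydrogenase gene Ldha at 1.08 but Ddit4 at -1.21, ribosomal proteins at 0.19, and the cell cycle at 0.16, with Ccnd1 at 0.95, the replication genes Cdc6 at 0.71 and Mcm7 at 0.64, and Mki67 at -0.16. Ribosomal proteins serve as a reference, so list medians of like size on this array carry little weight. That list lay inside the random range with the Feature Extraction ratio, at 0.078, and the value table, at 0.01. Tubb3 was at -0.58, Dcx at -0.49, Map2 at 0.06, Nes at -0.28 and Sox2 at -0.27, and Bmp4 was not well above background in either channel. The Feature Extraction ratio moved the fold of 18 of 71 measured named genes by over 1.5 times, all further from 0, with Dcx at -1.54, Slc35d3 at 2.47, Ankrd37 at 2.29, Pierce1 at -3.38, Aldh1l1 at -2.81 and Acta2 at -2.70; Ccnd1, at 1.01, passed the 2-fold limit. The remaining 12 lists, neuronal structure and synapse at -0.15 among them, lay inside the random range.

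Set side by side, the arrays ran in opposite directions. Over 10162 genes measured on both, r was -0.76 (-0.41 with the Feature Extraction ratio) and Spearman's rho -0.69 across genes, which are not independent replicates. The observed covariance was -0.115. A simulation of unchanged groups sharing a control, with the measured spot noise of SD 0.037, gave r = 0.33 and a covariance of 0.0014. Both simulated values follow from the noise put in. Gene-specific dye bias was not put in, and the spread between RNAs of separate cultures was not measured. The simulated values are therefore no benchmark for the size of the observed ones. Of genes at least 2-fold on both arrays, 161 were higher on the withdrawal array and lower on the other, where independent lists would share 5.29, and 31 were lower and higher, where they would share 0.266. Apoe, Tagln, Cyba, Mt2A and Pierce1 led the first set, and Cd93, Acss2, Slc35d3, Mvd and Acat2 the second. In the same direction, 11 genes had log2 ratios of at least 1 on both, where independent lists would share 1.37, and 0 were lower on both. The count in the same direction was 107 with the Feature Extraction ratio and 0 with probes well above background in both channels. These 11, led by Mrgprf, Milr1, Il22ra1, Or1e1 and the luteinizing hormone gene Lhb, were all well above background in red alone on both arrays, and for 3 of them the "at least" fold was under 2 on 1 array or both.

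**Figure D2:**
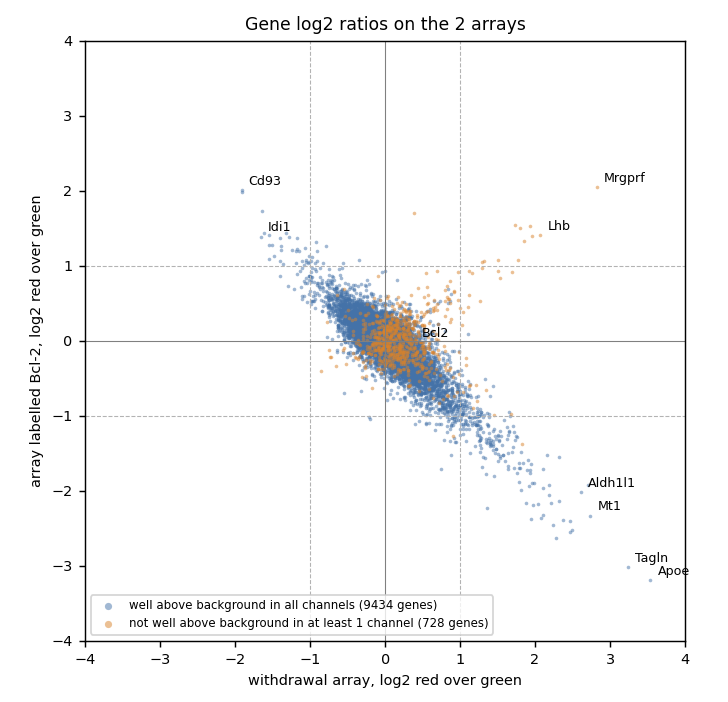
Log2 ratio of red over green of each gene on the withdrawal array (x axis) against the array labelled Bcl-2 (y axis), 1 point per gene, with dashed lines at the 2-fold limits. Blue points, 9434 genes well above background in all channels, run from upper left to lower right. Orange points are genes not well above background in at least 1 channel, whatever their direction. The 11 genes at least 2-fold higher on both arrays are among the orange points.

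The channels show where the labels and the signals part. Over 26861 spots well above background in all channels, the green channels of the arrays, labelled as the same control, differed with an SD of 0.40 on the log2 scale. The green channel of the array labelled Bcl-2 differed from the red channel of the withdrawal array with an SD of 0.14, and its red channel from the green channel of the withdrawal array with an SD of 0.15. The difference of the green channels followed the withdrawal ratio with a slope of 0.96, taken from different spots of the same 1117 probes.

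**Figure D3:**
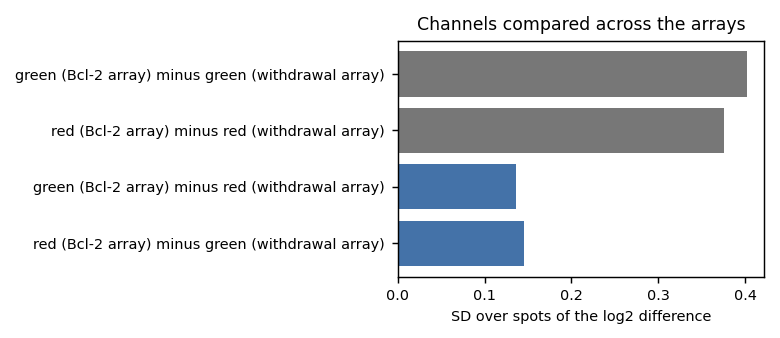
SD over 26861 spots of the log2 difference between a channel of the array labelled Bcl-2 and a channel of the withdrawal array. Channels of the same colour (grey) differ with SDs of 0.40 and 0.38, and channels of opposite colour (blue) with SDs of 0.14 and 0.15.

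The difference of the log2 ratios, array labelled Bcl-2 minus withdrawal array, set 15 of 24 lists apart, 3 higher and 12 lower. Cholesterol synthesis had a median difference of 2.27 (-2.27 with both signs turned), the astrocyte list -1.83, choroid plexus and ependyma -1.22, antioxidant and metallothionein -0.99 and p53 targets -0.85. With the red channels set against each other, the medians of these lists were nearer 0, at 1.03, -0.91, -0.60, -0.41 and -0.51. If both green channels held the same control, the difference of the log2 ratios sets Bcl-2 with bFGF against vector without bFGF. The green channels do not bear that out. With the sign of the withdrawal array alone turned, the difference becomes the sum of the ratios, which set 4 lists apart. Cholesterol synthesis then lies at -0.04, astrocyte at 0.09, choroid plexus and ependyma at -0.08, antioxidant and metallothionein at -0.02 and p53 targets at 0.13. With the other array alone turned, these values change sign.

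The product of the ratios of both arrays, as in the second column of the authors' deposited value table, was added after seeing the data. It sets red of the array labelled Bcl-2 against green of the withdrawal array if the remaining channels held the same RNA. On that reading the median of cholesterol synthesis was -0.04 and that of the astrocyte list 0.09, both inside the random range. The ribosomal protein list, which serves as a reference, stood apart at 0.24 (percentile 100), the median furthest from 0. Notch stood apart at 0.13, p53 targets at 0.13 and fibroblast and meninges at -0.13 (percentile 2.26), where Col1a2 was at -0.97. Since the reference list itself stood apart, medians of this size carry little weight. Bcl2 was at 0.37. Of 10162 genes, 64 were at least 2-fold higher and 5 lower, and 55 of the 64 were measured in red alone on at least 1 array. Among 9434 genes well above background in all channels, 9 were higher and 4 lower, all 9 and all 4 with the same sign on both arrays. Selection for a large product itself favours the same sign, so the signs cannot tell whether these genes reflect gene-specific dye bias. Such bias enters the product from both arrays and was not removed, so the genes and lists of this paragraph may reflect it. Named after their values were seen, Lyn at 1.52 was the highest of these, and Prrc2a at -1.26 and Prpf19 at -1.25 were the lowest.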

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

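All tests in this part were chosen after the result was seen, except that r between the arrays was a planned result; what each explanation predicts was written afterwards. In total, 192 genes were at least 2-fold on both arrays in opposite directions, a difference between the arrays that was not tested, since each comparison has 1 array. Apoe was at 3.54 and -3.20, and Acss2 at -1.92 and 1.99.

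Of the explanations weighed, a single control RNA in both green channels, as labelled, needs green channels that differ by noise alone; the slope of their difference on the withdrawal ratio, from different spots, was 0.96, which argues against it and so against opposite effects of the treatments on 1 control. Gene-specific dye bias would make the ratios correlate above 0, and r was -0.76. What stays open is whether the dyes were turned on the array labelled Bcl-2, or its green channel held RNA from cells without bFGF, the arithmetic of the authors' value table. After removing shared dye bias, the crossed channel pairs had SDs of 0.12 and 0.11, a quotient of 1.09, so these cannot be told apart: each pair may be a near repeat. Turned dyes on the withdrawal array in place of the other were not tested separately. With the dyes turned on either array, the Bcl-2 cells would resemble cells without bFGF, and with the other reading they would resemble vector cells with bFGF. Each of these statements takes as given that the array labelled Bcl-2 held RNA from Bcl-2 cells. Neither the channel values nor the Bcl2 probe checks that, so no conclusion on Bcl-2 cells is drawn.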

How the results depend on the processing

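The product of the ratios, the overlap in opposite directions and their alternatives were chosen after seeing the data. No paired analysis was possible because each comparison has 1 array. No spot was saturated, so leaving out saturated spots moved nothing. Median centring moved the median of all genes on the withdrawal array from 0.03 to 0.17. The medians of the cholesterol synthesis, astrocyte, p53, antioxidant and interferon lists kept their direction and stood apart on both arrays under every alternative run. Where values below differ from those reported and the construction of the setting does not show why, the cause was not tested.

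For the withdrawal array, counts higher were 445 with an offset of 10, 473 with median centring, 887 with the Feature Extraction ratio, 966 with the value table and 862 at 1.5-fold. Counts lower were 91, 237, 184 and 303 with the offset of 10, the Feature Extraction ratio, the value table and the 1.5-fold limit. For the array labelled Bcl-2, counts higher were 358, 307 and 235, and counts lower 690, 741 and 680, with the Feature Extraction ratio, the value table and the 1.5-fold limit. The other settings gave counts within 1.5 times.

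The correlation between the arrays stayed below 0: r was -0.77 without background correction, -0.66 with an offset of 10, -0.70 with median centring, -0.41 with the Feature Extraction ratio, -0.40 with the value table, -0.85 with probes well above background in both channels, -0.67 without a filter on dim probes, -0.77 with the brightest probe and -0.87 for genes above the median intensity. The overlap in the same direction was 21 with an offset of 10, 107 with the Feature Extraction ratio, 101 with the value table, 0 with probes well above background in both channels and 27 at 1.5-fold. In opposite directions it was 514, 523 and 664 with the Feature Extraction ratio, the value table and the 1.5-fold limit. In the product, counts higher were 135, 148, 344, 345 and 8 with the offset of 10, median centring, the Feature Extraction ratio, the value table and both channels well above background. Counts lower were 16, 13, 170 and 165 with the first 4 of these.

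Lists on the withdrawal array that no longer stood apart: neuronal structure and synapse at 0.23 with median centring; GABAergic markers at 0.33 with the Feature Extraction ratio and 0.29 with the value table. BMP and TGF-beta did so at 0.16 without background correction, 0.20 with an offset of 10, 0.20 with median centring, 0.090 with the Feature Extraction ratio, 0.18 with the value table, 0.091 with both channels well above background, 0.083 without a filter, 0.19 with the brightest probe and 0.19 as a mean. The BCL-2 family did so at 0.31 with median centring, 0.17 with the Feature Extraction ratio, 0.24 with the value table and 0.18 as a mean. Glycolysis and hypoxia response did so at -0.13 with an offset of 10, -0.17 with the Feature Extraction ratio, -0.10 with the value table and -0.076 as a mean, and turned to 0.17 with median centring.

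Lists on that array that came to stand apart: the cell cycle at -0.18 as a mean; FGF and ERK response at -0.12 with median centring, -0.26 with both channels well above background and -0.19 as a mean; the unfolded protein list at 0.19 with an offset of 10. Wnt did so at 0.34 with median centring, 0.47 with the Feature Extraction ratio, 0.54 with the value table and 0.34 as a mean. Oligodendrocyte lineage did so at 0.36 and 0.43, and microglia and blood at -0.37 and -0.30, with the Feature Extraction ratio and the value table. Fibroblast and meninges did so at 0.36 with an offset of 10, 0.36 with the Feature Extraction ratio, 0.30 with both channels well above background, 0.21 without a filter and 0.60 as a mean.

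On the array labelled Bcl-2, ribosomal proteins no longer stood apart at 0.078 with the Feature Extraction ratio and 0.01 with the value table. Neuronal structure and synapse came to stand apart at -0.20 with an offset of 10, -0.25 with median centring, -0.21 with the brightest probe and -0.27 as a mean. Neurogenic transcription factors did so at -0.13 without a filter, BMP and TGF-beta at -0.24 with the Feature Extraction ratio and -0.31 with the value table, Wnt at -0.13 without a filter and -0.25 as a mean, microglia and blood at 0.17 as a mean, and FGF and ERK response at 0.11 as a mean, against a median of -0.08. With red channels set against each other, the difference between the arrays no longer stood apart for neuronal structure at -0.040, Notch at -0.11, the BCL-2 family at -0.092 and ribosomal proteins at 0.070, and came to stand apart for FGF and ERK response at 0.21 and BMP and TGF-beta at -0.13.

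Of the named genes, 0 turned sign where called. Psat1 and Ldha on the array labelled Bcl-2 were under the 2-fold limit in 2 settings and 1 setting. In 53 pairs of a named gene and a setting, a gene under the limit reached it. On the withdrawal array Notch2 ranged from 0.84 to 1.57, Npy from 0.73 to 1.35, Enkur from 0.85 to 1.72 and Dcx from 0.58 to 1.46. On the array labelled Bcl-2 Dcx ranged from -1.61 to -0.49 and Gbp2 from -1.59 to -0.91.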

Other observations

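All tests in this part were chosen after the result was seen, while the cholesterol synthesis, FGF and ERK response and cell type marker lists themselves were planned. The 4 lists below, written after the top genes were known and seeded with some of them, are therefore not independent evidence. On the withdrawal array, fatty acid synthesis genes had a median log2 ratio of -0.69, and 4 of 13 measured members were at least 2-fold lower: Acss2, Scd, Elovl6 at -1.02 and Acly, which makes cytosolic acetyl-CoA, at -1.01. Ribosome biogenesis genes had a median of -0.58, with 24 of 24 below 0, among them Pprc1 at -1.21, Wdr43 at -1.07 and the nucleolar gene Gnl3 at -0.98; Myc, which drives many of them, was at -1.40. Contractile genes had a median of 0.44, with 12 of 12 above 0 and Acta2 at 2.19, Myl9 at 1.95 and Tpm2 at 1.27. Motile cilia genes had a median of 0.31, with Foxj1, Pierce1 and Rfx2 at 1.27 at least 2-fold higher among 11. On the array labelled Bcl-2 the medians were 0.46, 0.44, -0.54 and -0.31.

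Of 23 FGF and ERK response genes measured on the withdrawal array, 13 lay below 0 and 10 above. The lowest were Myc, Ccnd1 at -0.93, Phlda1 at -0.91, Egr1 at -0.78 and Dusp5 at -0.73, and the highest were Fgfr3 at 1.26 and Fosl1 at 0.92. These genes were picked after their values were seen. Of 15 astrocyte markers, 13 were well above background in the channel labelled vector with bFGF on the withdrawal array, and 2 are held by another list. Of 16 fibroblast and meninges markers 12 were, and of 11 choroid plexus and ependyma markers 7 were. Oligodendrocyte lineage had 11 of 15, microglia and blood 11 of 17, and endothelium and pericyte 2 of 14. Over all gene spots of that channel the share was 66.3%, counted per spot and not per gene. These counts therefore do not show which cell types were present.

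The cholesterol synthesis genes, lower on the withdrawal array as labelled, are a hypothesis to follow. The direction is not settled: with the sign of that array turned, their median would be 1.13, higher without bFGF. Gene-specific dye bias would leave about the same value in the average of both arrays' ratios per gene. The median of that average over the list was -0.019, against -1.13 on the withdrawal array, which argues against dye bias. It restates the opposite medians of the arrays and is no separate evidence. The cells without bFGF also changed medium, and no array changed the medium with bFGF kept, so loss of bFGF and change of medium cannot be told apart for the median of -1.13. For the direction as labelled alone, lipids supplied by the new medium are a candidate explanation that no array here tests.

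The 11 genes higher in red on both arrays were dim in green, which prompted a test of red-channel bias over every gene measured in red alone on the withdrawal array. Such bias alone would place over 90% of those 482 genes above 0 on both arrays, and 216 (44.8%) were. Among genes well above background in all 4 channels, 12.3% were. Opposite in sign were 47.1% of the genes measured in red alone, against 76.0% of those well above background in all 4 channels. The genes were selected for bright red and dim green on the withdrawal array, which itself favours values above 0 there. That selection cannot explain a share under 90%, but may explain one above 12.3%. The test therefore cannot tell whether such bias acted on some of those genes. On each reading of the channels left open above, a crossed pair would hold the same RNA. A difference between RNAs alone would then leave the 11 genes unexplained, since they were bright in red and dim in green on both arrays. This was not tested, and their cause remains open.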
